A study of Homo sapiens with 6 samples.

How the data were processed

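RNA-seq was done on 6 libraries of HBMEC, a human brain microvascular endothelial cell line per the labels. Total RNA was made into libraries with a NEBNext Ultra kit, per the labels' protocols. The sample titles mark 3 libraries as CON and 3 as OGD, each numbered 1 to 3. These are taken here as a control group kept under normal culture and a group after oxygen-glucose deprivation and reperfusion (OGD/R). The titles alone do not spell out the culture or the reperfusion. The length of the deprivation and of the reperfusion is not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

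The deposited values are whole-number read counts per Ensembl gene, in 1 table with a column per library. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2, SAMtools, featureCounts and edgeR, with no versions or settings. These notes give the genome build as GRCm38, which is a mouse build, while the IDs in the deposited table are human Ensembl genes. The build behind the counts is therefore uncertain, and no genome coordinates are printed. Whether counting used the strand of the reads, and how reads that match several genes were treated, is not given in the sources used here. Paralogs and overlapping genes can therefore share counts or lose them. The table held 17104 genes, of which 17093 matched a symbol in the gene name table. Each had at least 10 counts in at least 3 libraries, so low-count genes had been left out before deposit by a filter that is not stated. A gene with no value here was not analysed here, and nothing is said about its expression.

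Total counts were 32107917, 33607821 and 32404705 in control replicates 1, 2 and 3, and 34484647, 31048662 and 33935682 in OGD/R replicates 1, 2 and 3. Mitochondrially encoded genes took 4.94% to 5.33% of the counts, and the 10 most abundant genes of each library took 6.48% to 6.84%. Before averaging, the libraries were compared by a chi-square test over genes. The statistic per degree of freedom was 4.10 to 7.53 for pairs within a group and 16.3 to 23.9 for pairs across groups. No pair differed as little as sampling noise would give, so all 6 libraries were kept as separate samples.

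Counts were normalised by TMM and tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test was fitted with robust dispersions and without a replicate block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. filterByExpr, with its minimum count of 10, removed 0 genes. The common biological coefficient of variation was 6.26%. Levels are TMM-scaled CPM values, given as mean ± SD over 3 libraries. Fold changes are log2 of OGD/R over control, and their standard errors were derived from the fold change and the quasi-likelihood F statistic. A change of at least 2-fold means an adjusted p under 0.05 and an absolute log2 fold change of at least 1.

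In all, 26 gene lists were fixed from general knowledge before the data were examined. Each was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, against all other genes and with adjustment over the 26 lists. The test was repeated with the correlation estimated from the data, and fry was run beside it. Counts of changed members are given from the adjustment over all genes, and again adjusted over the list alone. Marker genes of 9 other cell types were fixed at the same time.

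Named genes follow a rule set before the data were examined. It took the 5 genes with the largest rise and the 5 with the largest fall, among changed genes with a mean of at least 5 CPM, groups that did not overlap and a protein-coding type of symbol. From each list past the camera threshold it took the 3 changed members with the smallest p, and from each other list 1 such member. Another 10 genes were fixed by name. Of these, CLDN5 has no value here. Some genes that the rule picked are not reported here. Further members are given as examples of a list and were picked after their values were seen.

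The alternatives set before the data were examined were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 3 libraries, leaving out mitochondrially encoded genes, the replicate number as a block, glmTreat for the 2-fold count, both other list tests, and leaving out each library in turn. The alternative without a filter tested the same genes as the main analysis and shows nothing about filtering. A correction for transcript length and GC content was added after seeing the data. It removed from each library a smooth trend (mgcv 1.9.3) on the length and GC content of each gene's longest GENCODE 29 transcript, known for 96.6% of the genes. The transcripts present in the cells can be shorter. The trends were fitted on 10859 protein-coding genes of sufficient expression, with an average log2 CPM above 2. Exons that overlap those of another gene were also counted from GENCODE 29, on either strand. Such an overlap can add reads of a neighbour, or lose a gene's own reads where those that match both genes were dropped. Among further genes named in the text, the overlap was at least 10% for ATP5PB (10.35%), WARS1 (10.57%), PROCR (12.85%), GAPDH (14.16%), HMGCS1 (14.95%), KRT18 (16.31%), ROBO4 (16.95%), MMP9 (18.41%), IL6 (20.69%), SQSTM1 (22.04%), CIITA (23.41%), MCM2 (23.62%), ICAM1 (23.64%), PRDX1 (24.9%) and HSPA1B (36.49%), whose counts can hold reads of a neighbour.

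The steps were tested on simulated counts of the same 17104 genes with known changes. The edgeR test recovered 38% of genes changed by a log2 of 0.25, 48% at 0.5, 76% at 1 and 90% at 2, with 50 genes at each size, and 2.72% of its calls were unchanged genes. With no simulated change it called 2 genes. Camera called 2 of 2 shifted lists and 1 of 23 unshifted ones. The simulated genes were independent of each other, so this does not test camera on lists whose genes vary together. A simulated length trend gave 235 false calls before the length and GC correction and 0 after it. That trend was the same in all OGD/R libraries and used the very lengths that the correction uses. It does not show how well the correction works on the real libraries, whose trends differ within a group. Small changes of single genes were therefore often missed in the simulation.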

Results

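Gene expression was measured by RNA-seq in cultured cells labelled as human brain microvascular endothelial cells (HBMEC), under control conditions and after OGD/R. In this cell model oxygen and glucose are withdrawn and then returned. Epithelial marker genes had a median CPM at least 30.5 times that of endothelial ones in every library, so the cell type stays open. There were 3 libraries per group, with 31048662 to 34484647 counts each. The only comparison in the design asks which genes differ after OGD/R. After OGD/R, the transcripts of cholesterol synthesis, mitosis and glycolysis were higher, and those of the ATF4-driven amino acid stress programme and of a list of angiogenic and Notch signalling genes were lower. Of 26 gene lists, 12 passed the camera test at its preset correlation and 0 with an estimated one. The changes were small, with a median absolute log2 fold change of 0.26 among the changed genes. The list of hypoxia-inducible genes did not pass its test, with 8 of 31 measured members higher and 4 lower.

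Of 17104 genes tested, 3370 (19.7%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 1749 of them higher and 1621 lower after OGD/R. The higher share was 51.9% with TMM and 39.7% when only total counts were used for scaling, which moved the split to 1383 higher and 2098 lower. Among the changed genes, 87.9% had an absolute log2 fold change under 0.5. In 5646 genes (33%) the 3 OGD/R libraries all lay on one side of the 3 control libraries, where chance gives 10%. The first principal component held 30.4% of the variance and separated the groups. Changes of at least 2-fold were found for 97 genes, 32 higher and 65 lower. This count was 22 with DESeq2 and 38 after a filter of at least 1 CPM in 3 libraries. A test against a 2-fold change itself (glmTreat) left 1 gene, SLC7A11 (adjusted p 0.000226). Without control replicate 3 the number of lower genes was 1079.

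The largest rise by the naming rule was that of FGFBP1 (ENSG00000137440), a carrier of fibroblast growth factors, from 3.71 ± 0.20 to 8.06 ± 0.18 CPM (mean ± SD, n = 3 each, log2 fold change 1.12 ± 0.16 SE, edgeR adjusted p = 2.52e-07). MT1F, a metallothionein, rose from 14.8 to 28.5 CPM (0.94 ± 0.10), and LIPG, endothelial lipase, from 4.40 to 8.08 CPM (0.88 ± 0.16). ACAT2, an acetyl-CoA acetyltransferase, rose from 54.6 to 99.7 CPM (0.87 ± 0.05), and PSMB9, an immunoproteasome subunit, from 22.7 to 41.3 CPM (0.86 ± 0.08). MT1F has near-identical relatives, and 52.3% of the ACAT2 exon bases overlap another gene, so both values are uncertain in source. The largest fall was that of SLC7A11 (ENSG00000151012), the cystine importer, from 79.7 ± 6.85 to 29.01 ± 3.64 CPM (−1.46 ± 0.07, adjusted p = 1.87e-17). NLRP1, an inflammasome sensor, fell from 11.98 to 5.16 CPM (−1.21 ± 0.14). BCAT1, the cytosolic branched-chain aminotransferase, fell from 49.9 to 23.7 CPM (−1.08 ± 0.07). HBEGF, an EGF receptor ligand, fell from 8.25 to 4.22 CPM (−0.97 ± 0.16), and SLC6A9, a glycine transporter, from 22.0 to 11.4 CPM (−0.95 ± 0.10). The groups did not overlap in any of these genes, because the naming rule required it. The same held for the other changed genes that it picked, by smallest p or by name.

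Of the 26 gene lists, 12 passed the camera test with its preset correlation, 8 towards higher and 4 towards lower expression. With the correlation estimated from the data, 0 lists passed, with adjusted p from 0.0731 to 0.484 for these 12, while 6 lists had an unadjusted p under 0.05. fry, which does not compare a list with other genes, called 17 lists.

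Genes of the integrated stress response, targets of the transcription factor ATF4 that serve amino acid supply and stress adaptation, were lower after OGD/R. Of 24 measured members, 17 fell and 0 rose (20 and 0 adjusted over the list alone), with a median log2 fold change of −0.41 (camera adjusted p = 2.91e-13). With an estimated correlation the adjusted p was 0.114. The serine synthesis enzymes PSAT1 and PHGDH fell from 164 ± 8.77 to 84.8 ± 3.73 CPM (−0.95 ± 0.05, adjusted p = 2.45e-20) and from 181 ± 12.8 to 105 ± 1.95 CPM (−0.79 ± 0.05, adjusted p = 1.33e-17). SLC7A11 belongs to the list as well. The growth factor GDF15 (−0.87), the kinase-like regulator TRIB3 (−0.53) and ATF4 itself (−0.32) also fell. DDIT3, which encodes the stress factor CHOP, had a value of −0.35 ± 0.15 and an adjusted p of 0.103. Its adjusted p was 0.0105 after the length and GC correction and 0.0105 to 0.533 over all alternatives, and 39.6% of its exon bases overlap another gene.

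Genes of cholesterol synthesis and uptake were higher. Of 21 measured members, 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.53e-13). The adjusted p was 0.114 with an estimated correlation. The late-pathway reductase DHCR7 rose from 166 ± 5.51 to 243 ± 3.69 CPM (0.55 ± 0.04). INSIG1, a sterol-regulated retention factor of the endoplasmic reticulum (ER), rose from 85.2 ± 3.70 to 133 ± 6.12 CPM (0.65 ± 0.05). The synthase gene HMGCS1 rose too (0.56).

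**Figure D1:**
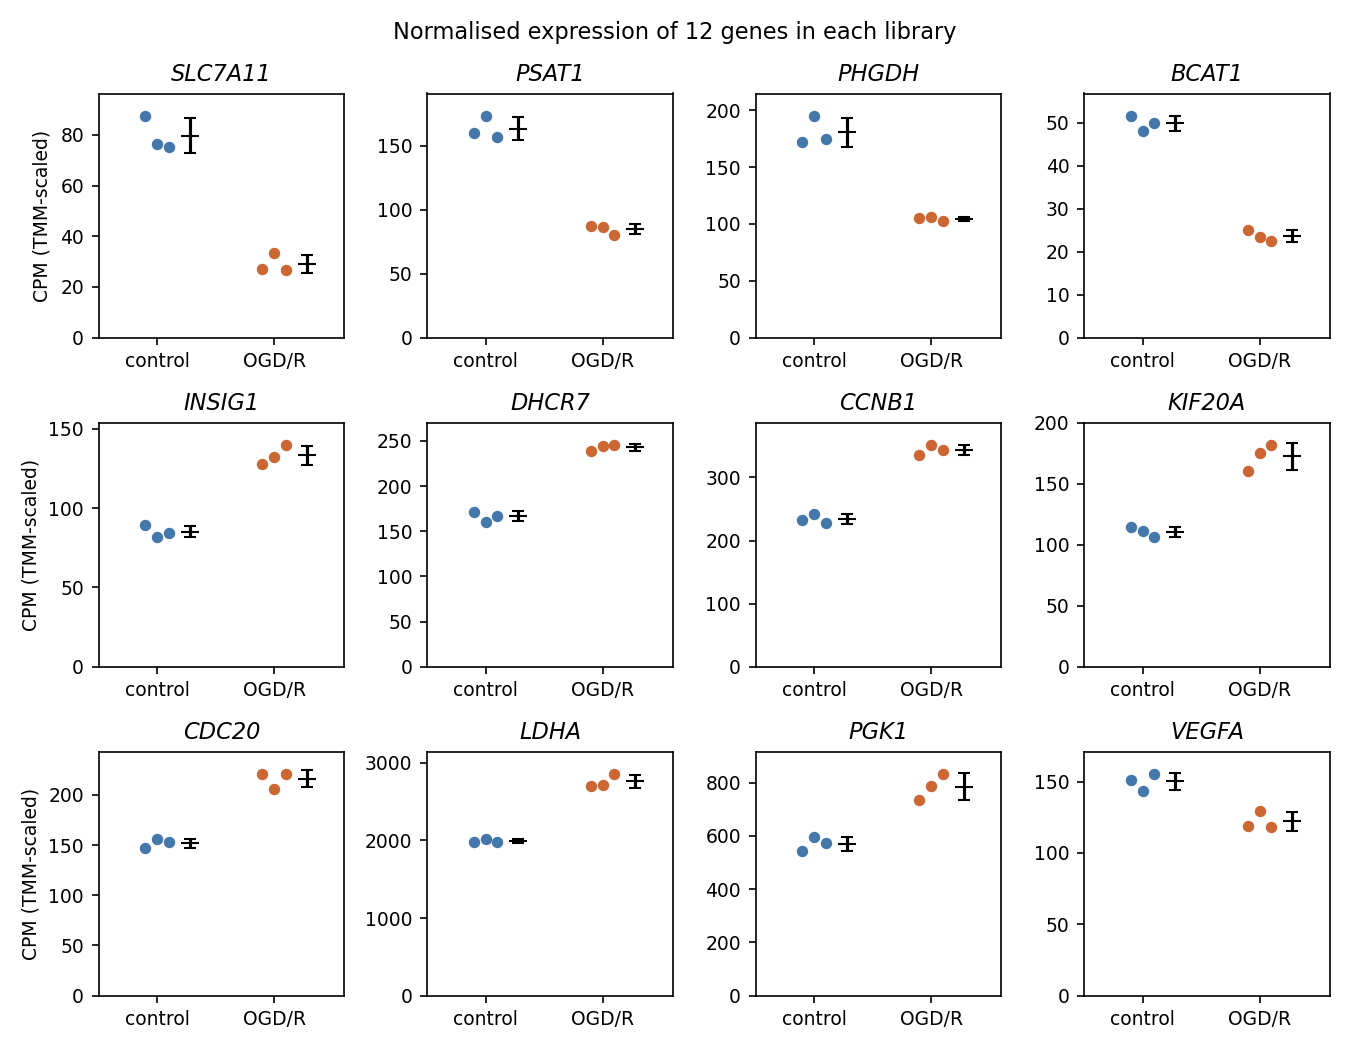
Normalised expression (CPM, TMM-scaled, linear axes from 0) of 12 named genes in each of the 3 control and 3 OGD/R libraries, with the mean and SD beside the points. SLC7A11, PSAT1, PHGDH, BCAT1 and VEGFA lie lower in all OGD/R libraries than in all control libraries, and the other genes lie higher.

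Mitotic genes were higher. Of 25 measured members, 24 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 2.46e-17). Camera gave an adjusted p of 0.0731 with an estimated correlation. KIF20A, a mitotic kinesin, rose from 111 ± 4.04 to 173 ± 11.1 CPM (0.64 ± 0.05), cyclin B1 (CCNB1) from 234 ± 7.56 to 344 ± 7.91 CPM (0.55 ± 0.04), and CDC20, an activator of the anaphase-promoting complex, from 152 ± 4.31 to 216 ± 8.38 CPM (0.51 ± 0.04). The remaining member, NUSAP1, was at 0.352 CPM in control with a fold change of −0.12 (adjusted p = 0.930), and 62.2% of its exon bases overlap another gene. Genes of DNA replication were higher as well. Of 26 measured members, 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 7.72e-05, and an adjusted p of 0.177 with an estimated correlation). The nucleotide reductase subunit RRM1 (0.34 ± 0.04), the sliding clamp PCNA (0.29 ± 0.04) and thymidylate synthase TYMS (0.32 ± 0.06) rose, although 46.6% of the TYMS exon bases overlap another gene. PCNA was at 0.14 after the length and GC correction. Of the replicative helicase genes, MCM7 rose (0.17), while MCM2 (0.03) and MCM4 (0.03) did not pass.

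Glycolytic genes were higher. Of 18 measured members, 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 3.58e-05). The adjusted p was 0.151 with an estimated correlation. LDHA, lactate dehydrogenase A, rose from 1995 ± 23.4 to 2761 ± 86.7 CPM (0.47 ± 0.04), PGAM1 from 478 ± 12.1 to 662 ± 2.33 CPM (0.47 ± 0.04) and PGK1 from 571 ± 26.0 to 786 ± 49.7 CPM (0.46 ± 0.04). GAPDH, often used as a reference gene, rose by 0.19 ± 0.04 (adjusted p = 0.000379). HK2, an inducible hexokinase, was the member that fell (−0.29). Hypoxia and HIF targets as a list did not pass (camera adjusted p = 0.947). Of 31 measured members, 8 rose and 4 fell (8 and 4 adjusted over the list alone). The median was −0.01 and the mean 0.00, while the direction of the test was upwards. BHLHE40 (0.31), CAVIN1 (0.24) and BNIP3 (0.23) were among the 8 that rose. LDHA, PGAM1 and PGK1 were counted in the glycolysis list and not in this one. STC2, a secreted stanniocalcin, fell from 202 ± 2.55 to 124 ± 5.50 CPM (−0.71 ± 0.04). VEGFA, the main angiogenic growth factor, fell from 150 ± 5.95 to 122 ± 6.57 CPM (−0.30 ± 0.05, adjusted p = 2.91e-06), and was at −0.13 after the length and GC correction. SLC2A1, the glucose transporter GLUT1, had a value of −0.08 ± 0.05 (adjusted p = 0.225).

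Genes of the nuclear-encoded respiratory chain were higher, with 22 of 34 measured members rising and 0 falling (23 and 0 adjusted over the list alone) and a median of 0.21 (camera adjusted p = 1.63e-07, and an adjusted p of 0.239 with an estimated correlation). The ATP synthase subunits ATP5F1B (0.25 ± 0.04), ATP5PB (0.26 ± 0.04) and ATP5F1C (0.28 ± 0.05) were among them. After the length and GC correction the median was 0.11, and ATP5F1C, at 0.10, no longer passed (adjusted p 0.0596, and 1.12e-07 to 0.0596 over all alternatives). Cytosolic ribosomal protein genes had 24 of 40 members higher and 0 lower (32 and 0 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 1.63e-07). The adjusted p was 0.484 with an estimated correlation and 0.122 by fry, and the median was 0.07 after the length and GC correction. RPL23 (0.28), RPS16 (0.25) and RPS23 (0.25) had the smallest p, and reads of these genes can be shared with their many pseudogenes.

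In the respiratory chain and ribosomal protein lists the longest annotated transcripts were short, with median lengths of 2097 and 1917 nucleotides. Fold change fell with transcript length, taken for each gene from its longest annotated transcript. Where the cells hold a shorter one, the length and GC correction can be incomplete. Across 10859 genes, Spearman's rho of the fold change with length was −0.36, and that with GC content was −0.08; genes are not independent replicates. The median log2 fold change was 0.13 in the shortest of 10 equal groups of genes and −0.10 in the longest. Each library's own deviation from the mean had a rho with length of 0.44, 0.04 and 0.29 in control replicates 1, 2 and 3, and of −0.28, −0.33 and −0.23 in OGD/R replicates 1, 2 and 3. After the correction, chosen after seeing the data, 3296 genes passed, of which 2395 had also passed in the same direction without it. The medians of the stress response, cholesterol and mitosis lists were then −0.44, 0.43 and 0.34.

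**Figure D2:**
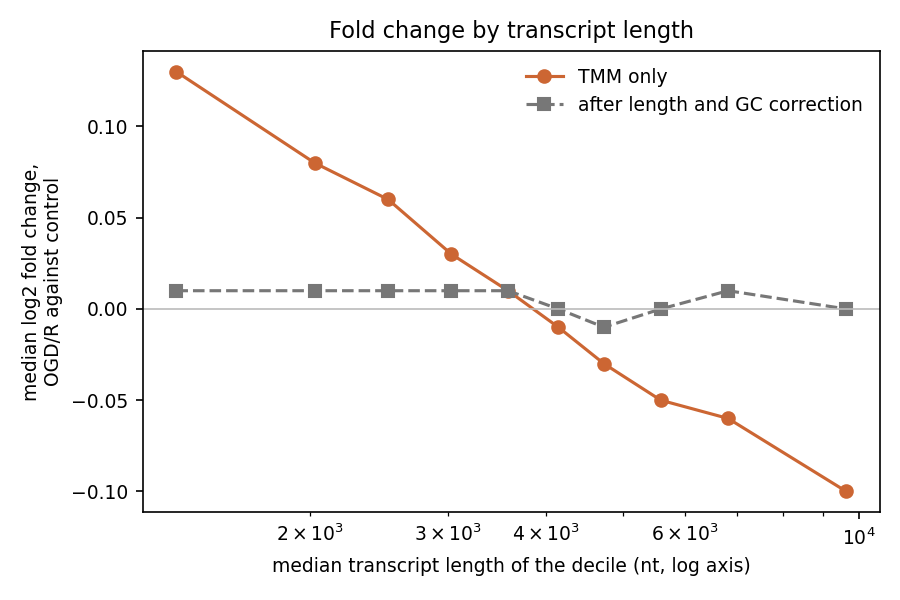
Median log2 fold change, OGD/R against control, in 10 equal groups of genes ordered by the length of the longest annotated transcript (nucleotides, log axis), with TMM alone (circles) and after the length and GC correction (squares). The medians run from 0.13 in the shortest group to −0.10 in the longest with TMM alone, and lie between −0.01 and 0.01 after the correction.

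Interferon-stimulated genes were higher as a list, although few members passed singly. Of 25 measured members, 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 5.33e-05). With an estimated correlation the adjusted p was 0.114. The antiviral synthetase OAS3 (0.30 ± 0.05) and the RNA sensor IFIH1 (0.32 ± 0.07) rose. In the heat shock list, 7 of 19 measured members rose and 3 fell (7 and 3 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.0269, and an adjusted p of 0.177 with an estimated correlation). HSPB1 rose from 205 ± 2.04 to 281 ± 8.55 CPM (0.46 ± 0.04), and the HSP90 genes HSP90AA1 (0.44 ± 0.04) and HSP90AB1 (0.31 ± 0.04) rose. The classically heat-inducible HSPA1A (−0.21), HSPA1B (−0.32) and DNAJB1 (−0.21) fell, and reads can be shared between HSPA1A and HSPA1B. The heat shock call ended after the length and GC correction (median 0.10, adjusted p 0.0867), with the replicate number as a block (0.11, 0.0587) and without OGD/R replicate 3 (0.08, 0.0528), so the call was lost while the median moved little, with adjusted p within 0.00118 to 0.177 over all alternatives.

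Angiogenic and Notch signalling genes were lower. Of 20 measured members, 9 fell and 2 rose (9 and 3 adjusted over the list alone), with a median of −0.22 (camera adjusted p = 0.00225). Camera gave an adjusted p of 0.116 with an estimated correlation. The Notch ligands JAG1 and JAG2 fell from 49.8 ± 1.19 to 33.5 ± 1.01 CPM (−0.57 ± 0.07) and from 122 ± 3.13 to 91.0 ± 4.43 CPM (−0.43 ± 0.05). The receptor NOTCH1 fell from 54.1 ± 4.25 to 37.9 ± 1.98 CPM (−0.51 ± 0.07), and the Notch targets HES1 (−0.78), HEY1 (−1.73, from 0.950 to 0.284 CPM) and NRARP (−0.45) fell as well. NOTCH1 was at −0.33 and JAG2 at −0.29 after the length and GC correction. APLN (0.56) and PDGFB (0.21) rose.

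Matrix proteases and their inhibitors were lower as a list. Of 18 measured members, 7 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of −0.18 (camera adjusted p = 0.00425, and an adjusted p of 0.177 with an estimated correlation). The median was −0.07 (adjusted p 0.0390) after the filter of at least 1 CPM in 3 libraries, so low-count members carry part of it, and −0.21 to −0.07 over all alternatives. The gelatinase gene MMP9 fell from 54.1 ± 6.60 to 39.4 ± 3.17 CPM (−0.46 ± 0.07). TIMP1, a metalloprotease inhibitor, rose from 334 ± 15.6 to 398 ± 6.65 CPM (0.25 ± 0.04), and was at 0.12 after the length and GC correction. In the pyroptosis and inflammasome list, 3 of 12 measured members fell and 0 rose (3 and 0 adjusted over the list alone), with a median of −0.19 (camera adjusted p = 0.0271, and an adjusted p of 0.177 with an estimated correlation). These were NLRP1, the cytokine gene IL1B (−0.51 ± 0.06) and the gasdermin gene GSDME (−0.38 ± 0.07). This call ended without control replicate 2, where the median was −0.10 (adjusted p 0.0831, within 0.00499 to 0.177 over all alternatives).

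**Figure D3:**
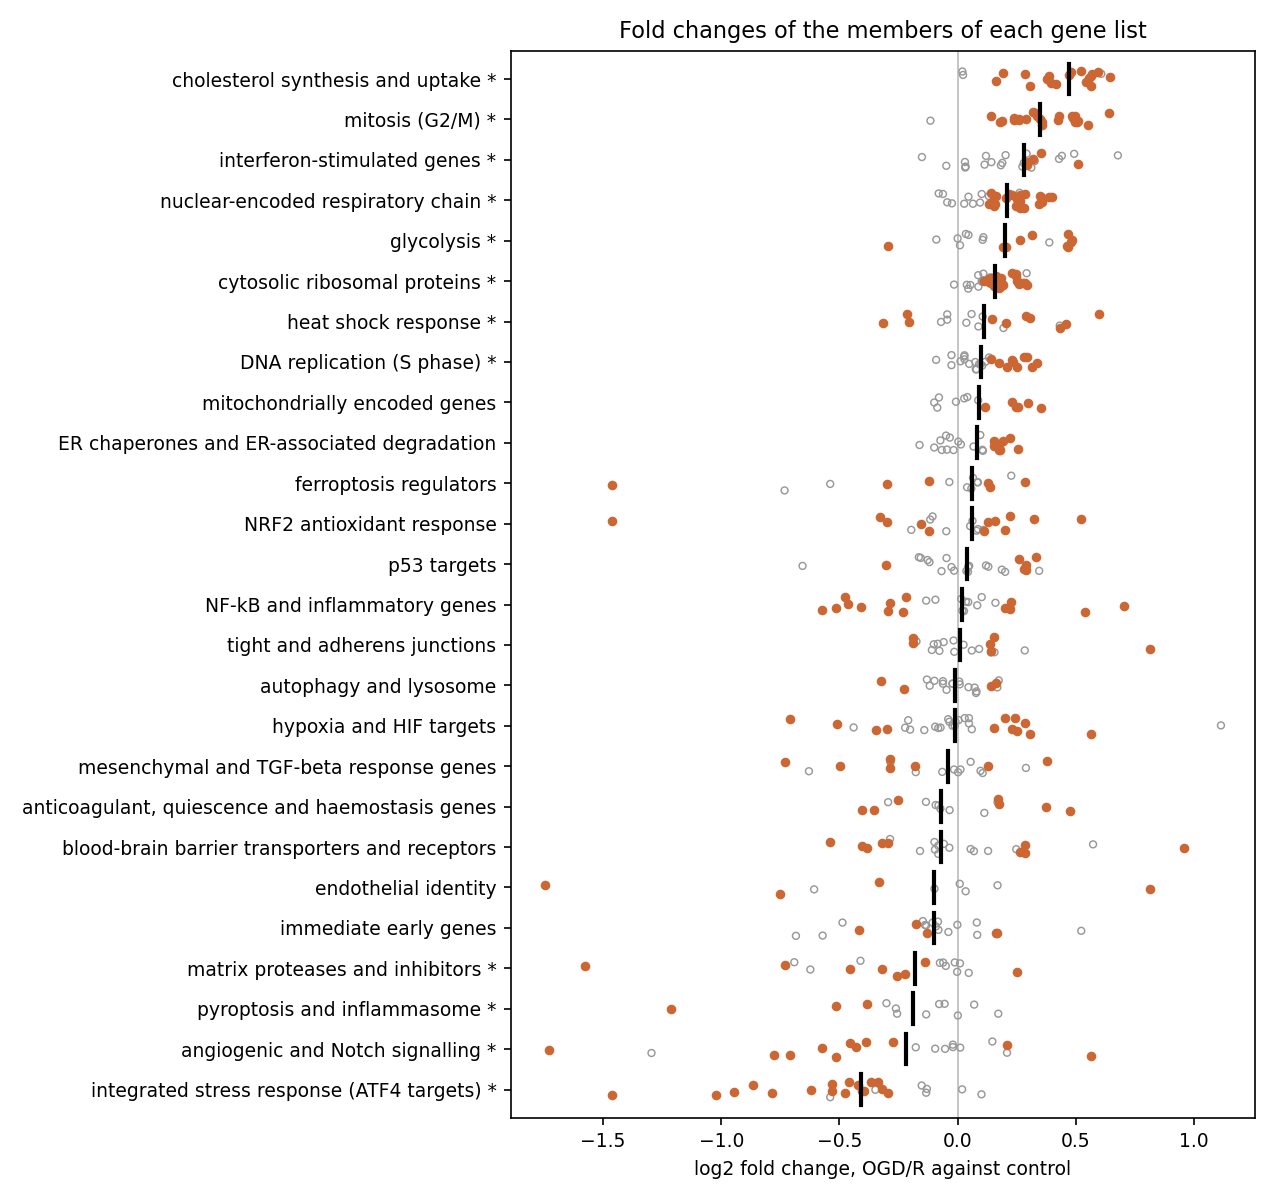
Log2 fold changes, OGD/R against control, of the measured members of each of the 26 gene lists (filled points, adjusted p under 0.05; open points, not past the threshold; black bar, median; asterisk, list past the camera test with the preset correlation). The cholesterol and mitosis lists lie highest, with medians of 0.47 and 0.35, and the integrated stress response list lowest, with −0.41.

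The other 14 lists did not pass. Tight and adherens junction genes had 4 of 20 members higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.678). CDH5, which encodes VE-cadherin, rose from 10.3 ± 1.00 to 18.1 ± 3.17 CPM (0.81 ± 0.11, adjusted p = 2.71e-07). OCLN, which encodes occludin, had a value of −0.08 ± 0.06 (adjusted p = 0.418), and TJP1, which encodes ZO-1, of −0.01 ± 0.05 (adjusted p = 0.889). The sign of TJP1 turned after the length and GC correction (0.07) and without control replicate 1 (0.03). Blood-brain barrier transporters and receptors had 4 of 22 members higher and 5 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.409). The large neutral amino acid transporter SLC7A5 fell from 936 ± 29.6 to 707 ± 24.6 CPM (−0.41 ± 0.04), and the transferrin receptor gene TFRC rose (0.29). NF-kB and inflammatory genes had 5 of 25 members higher and 9 lower (7 and 9 adjusted over the list alone, camera adjusted p = 0.900). LTB, lymphotoxin beta, rose from 31.6 ± 1.43 to 51.5 ± 5.59 CPM (0.70 ± 0.07), and the chemokine gene CCL2 rose (0.54), while IL6 (−0.29) and CXCL8 (−0.23) fell. ICAM1, a leukocyte adhesion molecule, had a value of −0.09 ± 0.05 (adjusted p = 0.163). ICAM1 passed without control replicate 1 (−0.14, adjusted p 0.0421, and 0.0421 to 0.778 over all alternatives).

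Among antioxidant genes of the NRF2 list, 7 of 21 rose and 5 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.900). HMOX1, haem oxygenase 1, fell from 56.2 ± 1.15 to 45.7 ± 3.49 CPM (−0.30 ± 0.06, adjusted p = 0.000330), and PRDX1 (0.52) and TXN (0.32) rose. Ferroptosis regulators had 3 of 15 higher and 3 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.907), with SLC7A11 the member of the smallest p. For the NF-kB, transporter, NRF2 and ferroptosis lists, the median, the mean and the direction of the test differed in sign. ER chaperones had 8 of 22 higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.0575), with HSP90B1 at 0.22 ± 0.04 and HSPA5, which encodes BiP, at 0.01. This list passed with upper-quartile scaling (adjusted p 0.0453) and with limma-voom (0.0206), and had 6 members higher and 2 lower after the length and GC correction (0.210). Mitochondrially encoded genes had 6 of 13 higher and 0 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0575). MT-CO2 was at 0.35 ± 0.04 and at 0.12 after the length and GC correction. The list had 1 member higher and 5 lower after that correction, with a median of −0.04 against 0.09 before it (adjusted p 0.0867, direction downwards). It passed without OGD/R replicate 1 (0.0123) and with limma-voom (0.00214), within 0.00214 to 0.484 over all alternatives. Mesenchymal and TGF-beta response genes had 2 of 18 higher and 5 lower (2 and 6 adjusted over the list alone, camera adjusted p = 0.0623). The fibronectin gene FN1 fell (−0.50). This list passed without control replicate 3 (adjusted p 0.0372) and with limma-voom (0.00934), within 0.00690 to 0.280 over all alternatives.

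Immediate early genes had 2 of 20 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.262), with JUN at −0.42 ± 0.06. p53 targets had 5 of 24 higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.272), with PLK2 at 0.33 ± 0.04 and CDKN1A, the gene of p21, at 0.04. Autophagy and lysosome genes had 2 of 20 higher and 2 lower (3 and 3 adjusted over the list alone, camera adjusted p = 0.907), and SQSTM1, an autophagy receptor, was at −0.33 ± 0.04. Anticoagulant, quiescence and haemostasis genes had 4 of 15 higher and 3 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.900). NT5E, the ectonucleotidase CD73, fell (−0.41 ± 0.04), and PROCR, the endothelial protein C receptor, rose (0.47).

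Endothelial identity genes had a median of 3.73 to 6.76 CPM in the 6 libraries. Of the 25 fixed, 9 had a value here, and 1 of these rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.409). CDH5 was the gene that rose, and ROBO4 (−0.75), SOX18 (−0.33) and MMRN2 (−1.75, from 0.717 to 0.207 CPM) fell. The most abundant were ENG, at 78.4 and 80.3 CPM in control and OGD/R (0.03, adjusted p 0.740), and EGFL7, at 52.7 CPM in control (0.01, adjusted p 0.952). Epithelial markers had a median of 189 to 231 CPM, midway between EPCAM and KRT7. KRT8, a simple-epithelial keratin, rose from 1235 ± 68.2 to 1555 ± 21.1 CPM (0.33), KRT18 from 848 ± 28.2 to 962 ± 9.26 CPM (0.18) and KRT7 from 356 ± 27.2 to 400.1 ± 7.24 CPM (0.17). EPCAM was at 52.4 and 57.7 CPM (0.14, adjusted p 0.0849), below ENG. CLDN4, a claudin, was at 21.2 and 17.8 CPM (−0.25, adjusted p 0.0658), and CDH1, the gene of E-cadherin, at 1.19 and 0.980 CPM (−0.28, adjusted p 0.646), below CDH5. In all, 6 of 8 epithelial markers had a value, with 3 higher and 0 lower. The ratio of the epithelial to the endothelial median CPM was 30.5, 31.4 and 34.4 in control replicates 1, 2 and 3. In OGD/R replicates 1, 2 and 3 it was 46.9, 49.1 and 60.5. The endothelial median is the level of 1 gene of 9. By group means this was ROBO4 in control (6.36 CPM) and FLI1 in OGD/R (4.15 CPM). The rise of the ratio therefore does not show a shift of the whole endothelial list.

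Of the markers of other cell types, 5 of 10 pericyte or smooth muscle genes, 1 of 9 fibroblast, 2 of 8 neuronal, 1 of 10 microglial or macrophage, 1 of 7 oligodendrocyte and 1 of 6 lymphatic endothelial genes had a value, and 0 of these changed or had an unadjusted p under 0.05 in edgeR. Among 3 of 8 astrocyte markers with a value, SOX9, a transcription factor of several tissues, fell from 211 to 184 CPM (−0.20). None of the 6 erythroid markers had a value here.

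**Figure D4:**
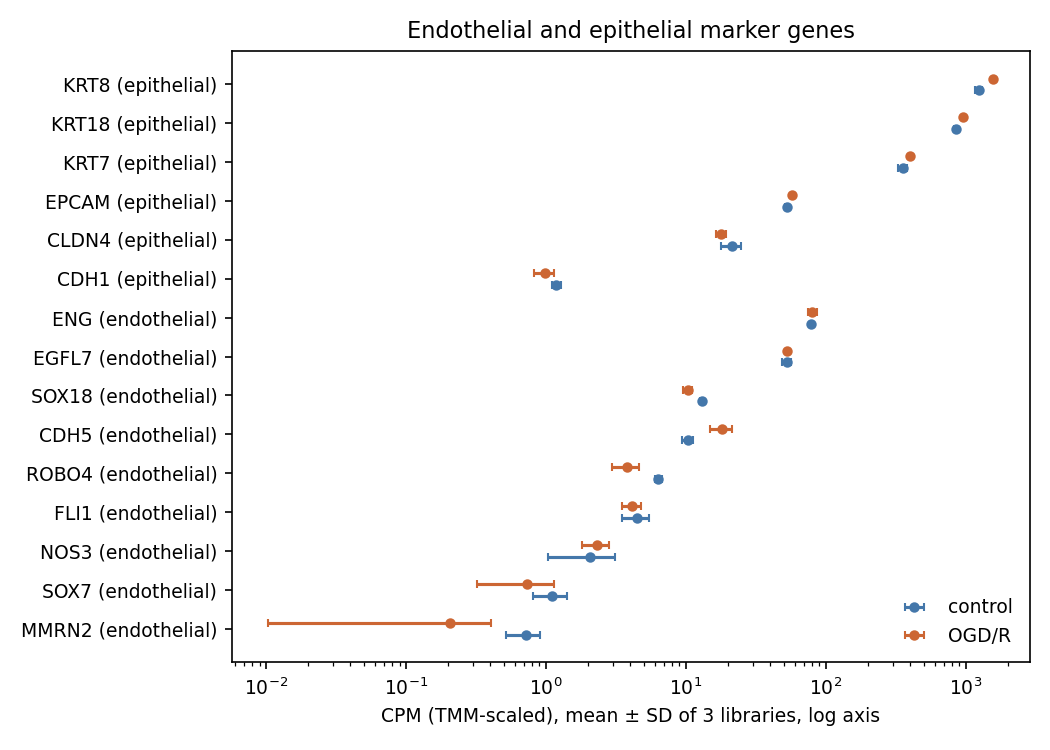
Expression of the measured endothelial identity and epithelial marker genes (CPM, TMM-scaled, log axis; points, mean of 3 libraries; bars, SD, with the lower bar shortened where it would reach 0) in control and OGD/R. KRT8, KRT18 and KRT7 lie at 356 to 1555 CPM in both groups, while CDH5 lies at 10.3 and 18.1 CPM.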

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

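The length and GC correction was chosen after seeing the data; the other alternatives were not. The number of changed genes was 3296 to 3529 over all alternatives with 6 libraries, and 2383 to 3367 when 1 library was left out, with 1293 to 1840 higher and 1079 to 1527 lower. The lowest count of lower genes, 1079, came without control replicate 3. The count of at least 2-fold changes fell from 97 to 22 with DESeq2 (the cause was not tested), to 38 with at least 1 CPM in 3 libraries, where fewer low genes were tested, and to 1 with glmTreat, which tests against 2-fold itself. It was 74 to 105 with 1 library left out. Lists past the camera test at its preset correlation numbered 11 to 15 with 6 libraries, and 11 to 13 with 1 library left out. The 15 came with limma-voom, which added the ER chaperone, mitochondrially encoded and mesenchymal lists. With an estimated correlation 0 lists passed, and the cause was not tested. Total-count scaling moved the share of higher calls from 51.9% to 39.7%. Whether depth limits these counts was not tested.

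The labels do not say that the replicate numbers pair the samples. Residual correlations of same-numbered libraries were 0.006, 0.017 and 0.026. These lay under the bound of 0.1 used for pairing. Each control library correlated best with the OGD/R library of its own number, but values so near 0 do not show pairing. With the replicate block, 3529 genes (1827 higher, 1702 lower), 108 at least 2-fold changes and 11 lists were called. The heat shock list, with an adjusted p of 0.0587 and an unchanged median of 0.11, was no longer called, and no other call of a list or named gene changed.

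Direction reversed for some lists near 0 that did not pass in either case, and the cause was not tested. The direction of the hypoxia test turned at medians of −0.04 (total counts only), −0.02 (limma-voom) and −0.01 (the CPM filter and fry), and with libraries left out the median was −0.03 to 0.02. The anticoagulant list turned at −0.07 (limma-voom) and ran from −0.08 to −0.01 with libraries left out, and ferroptosis turned at 0.06 (replicate block) and ran from 0.01 to 0.08. NF-kB genes ran from −0.05 to 0.05 with libraries left out. The NRF2 list turned at 0.00 (length and GC) and 0.06 (fry) and ran from 0.02 to 0.08, autophagy turned at −0.01 (length and GC) and ran from −0.02 to 0.01, and mitochondrially encoded genes turned at −0.04 (length and GC). The fold change of TJP1 turned to 0.07 (length and GC) and ran from −0.04 to 0.03 with libraries left out. Of the named genes' values under alternatives, 986 kept direction and side of the threshold, 2 reversed, 2 gained and 1 lost a call.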

Other observations

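The length and GC correction, the random lists matched on length, the list medians within libraries, the marker ratio test with its bound, the interferon-gamma list and the proteasome list were tests chosen only after related results were seen. Proteasome core genes, which form the constitutive 20S particle, were higher after OGD/R, with 12 of 14 rising, 0 falling and a median log2 fold change of 0.37 (camera p = 7.31e-09, and p = 0.102 with an estimated correlation). PSMB3 (0.53), PSMB6 (0.43) and PSMA4 (0.42) were among them, and the median was 0.25 after the length and GC correction. Of 21 genes of the interferon-gamma response and antigen processing, 12 rose and 1 fell, with a median of 0.26 (camera p = 5.62e-05, and p = 0.0761 with an estimated correlation). The guanylate-binding proteins GBP1 (0.81) and GBP2 (0.66), the proteasome activator PSME2 (0.45) and the peptide transporter TAP1 (0.28) rose, while the tRNA synthetase WARS1 fell (−0.22). CIITA (−0.30) and IDO1 (−0.05) did not pass. The list was made after the values of PSMB9 and several other members had been seen, so it is no independent evidence of its direction.

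Fatty acid synthesis genes under the control of SREBP, the factor that also drives cholesterol synthesis, were higher too, with 9 of 14 rising and 0 falling. SCD (0.39), FADS2 (0.53), ELOVL6 (0.44) and FASN (0.30) were among them, and SREBF1 was at −0.01. Charging enzymes of tRNA moved apart. Of 13 cytosolic synthetases that general knowledge places under ATF4, 9 fell and 0 rose (median −0.24, camera p = 9.71e-06, and p = 0.133 with an estimated correlation), among them IARS1 (−0.35) and SARS1 (−0.35). Of 7 others, 4 rose and 0 fell (median 0.19, camera p = 0.00198, and p = 0.140 with an estimated correlation), among them RARS1 (0.30). The median of these 7 lay inside the range of 95% of random lists matched on length and expression (−0.08 to 0.21, percentile 94.8), so length is not excluded as its cause. After the length and GC correction their median was 0.13 (camera p = 0.00976 at the preset correlation).

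The fall of fold change with transcript length was weighed as the cause of 5 list results. It is argued against as the whole cause for the stress response, cholesterol synthesis and mitosis lists. The medians of 4 lists before the correction were −0.41 for the stress response, 0.47 for cholesterol synthesis, 0.35 for mitosis and 0.21 for the respiratory chain. These lay outside the range that held 95% of 10000 random lists of the same length and expression. For the respiratory chain that range was 0.00 to 0.15. Ribosomal protein, respiratory chain and proteasome genes were kept out of all random lists. As these are mostly short genes that rose here, leaving them out may lower the ranges. The medians after the correction were −0.44, 0.43, 0.34 and 0.11 (camera adjusted p = 7.14e-15, 4.54e-14, 5.46e-17 and 4.60e-05). The median of each list taken within each library still parted the groups then, by −0.41 ± 0.03 (SE), 0.43 ± 0.02, 0.33 ± 0.01 and 0.12 ± 0.03, and the groups did not overlap. For the respiratory chain, down from 0.21, the trend may be part of the cause, and whether it is the whole cause stays open. Its members called higher went from 22 to 13 after the correction. Its random lists held no respiratory chain genes, and lengths are those of the longest annotated transcripts. For ribosomal protein genes the trend may be the whole cause, since the median went from 0.16 to 0.07. Matched random lists, with ribosomal genes kept out, had a median of 0.16 themselves (95% of lists from 0.08 to 0.21, percentile 39.8). Within libraries, the ribosomal medians differed by 0.16 ± 0.07 before the correction and by 0.07 ± 0.05 after it, and the groups then overlapped. The bound set beforehand against length, an adjusted p under 0.05 after the correction, was met by all 5 lists (0.00174 for ribosomal genes). It was a poor bound for all of them, because the preset correlation can be too low for genes that vary together. With an estimated correlation the adjusted p after the correction was 0.0684, 0.129, 0.0161 and 0.290 for the 4 lists and 0.648 for ribosomal genes, so only mitosis passed, and before it 0 of the 5 passed. The verdicts therefore rest on the random lists together with the spread between libraries. For the respiratory chain they also allow for the genes kept out of its random lists. The random lists drew their genes singly, so their range can be too narrow for genes that vary together. Only the spread between libraries allows for such genes. The heat shock list, at 0.11, lay inside the range of its random lists (−0.03 to 0.17, percentile 73.1), but unlike the ribosomal list it kept a median of 0.10 after the correction and within libraries a difference of 0.09 ± 0.02, with groups that did not overlap, so the part of length in it stays open. Fragmentation of RNA, size selection of the libraries and a true change in long transcripts all stay open as sources of the trend, which parts the libraries as the groups do.

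The stress response and cholesterol results were each tested against a change in 1 regulator. Lower ATF4 activity predicted lower values for the ATF4-controlled synthetases than for the others, and the medians differed by −0.43 (exact one-sided permutation over genes, p = 0.00108, which is too small because genes of 1 programme are not independent). The permutation used fold changes before the length and GC correction. The median lengths were 3592 nucleotides for the ATF4-controlled genes and 2421 for the others, so length can add to the difference. After the correction the medians were −0.23 and 0.13, and the permutation was not repeated. Higher SREBP activity predicted a rise of the fatty acid genes, and their median was 0.22 (camera p = 7.03e-07, and p = 0.0120 with an estimated correlation); that list was fixed before its values were seen, except for ME1, a member of the NRF2 list. Both results are consistent with these hypotheses, which were formed on the same libraries. Fresh medium or another serum level in the OGD/R cells could give both changes, and stays as open as an effect of the deprivation itself, since no sample here separates them.

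The median CPM of the epithelial markers was 30.5 times that of the endothelial ones or more in every library. The markers did not part as classes, since the epithelial median lies midway between EPCAM and KRT7, ENG (78.4 CPM in control) lay above EPCAM (52.4) and CDH5 (10.3) above CDH1 (1.19). A small admixture of epithelial cells cannot be told apart from other explanations by this ratio, which is the pattern itself and whose bound was set after it had been seen. It rests on 9 endothelial and 6 epithelial genes with a value, genes not analysed here limit it, and KRT8, KRT18 and KRT7 can also be made by cultured endothelial cells. Whether these are endothelial cells with low endothelial transcripts or mostly cells of another type stays open, and no biological explanation was tested.

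Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many changed genes (3370, against at most 1 in the others), as many at least 2-fold changes (97, against at most 1) and as many lists (12, against at most 4). With 10 splits the share cannot fall under 0.05.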
